A study of Mus musculus with 9 samples.

How the data were processed

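Polyadenylated RNA of bEnd.3 cells was sequenced from 9 samples, 3 for each of PSS, HSS and Vortex flow. Per the labels' protocols, RNA was extracted with TRIzol, 1.5 µg per sample entered library preparation with a NEBNext Ultra kit, and the RNA sent for sequencing was described as mixed. Per the submitters' processing notes the tools were HISAT2 and HTSeq 0.13.5 with the genome build GRCm39. The strand setting is not given in the sources used here. The authors deposited 1 table of 31232 genes with a whole-number count per gene and library, as made by HTSeq without normalization. The same deposited table holds FPKM values, which the authors scaled by gene length and column total. This was checked: in 100% of genes with values, count, FPKM and column total gave 1 whole-number gene length within a relative tolerance of 1e-06. Samples were assigned to groups from the labels and column names. Counts per library ranged from 17407217 to 22965802. No other sample columns were left unused.

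Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 3 groups, which left 15774, and libraries were scaled by TMM. A negative binomial quasi-likelihood model with robust estimation was fitted to all 9 libraries with 1 mean per group, and each pair of groups was compared by the quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The biological coefficient of variation was 0.350. Standard errors were taken as the log2 fold change divided by the square root of F. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1, so p-values for single genes rest on the variance model that edgeR shares across genes. CPM values use TMM-scaled library totals, with a prior count of 2 on the log scale. Where 1 group had 1 to 3 counts of a gene, the ratio of scaled counts is given with an exact 95% interval, and where it had none, a bound against 3 counts over the group.

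Gene lists were written from general knowledge before the data were examined, as were the groups, comparisons, tests, thresholds, the rule for named genes and most alternatives. Of 37 lists, 36 had the minimum of 5 tested members. The lymphatic list had 4 and was not tested. Lists were tested with camera in limma 3.58.1 against all other tested genes, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data. They were also tested with fry, which asks whether the genes of a list move on balance in 1 direction. Adjusted p-values of lists are by the Benjamini-Hochberg method over the 36 lists of a comparison. The counts adjusted over the list alone apply the same adjustment to its tested members. List members were matched by symbol, and 35 symbols occur more than once in the table. Reads shared between close paralogs, as among the Saa, Sprr2, Prl2c, class I histocompatibility and Hspa1 genes, make their values uncertain.

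Genes were named by a fixed rule. For HSS against PSS and Vortex against PSS it takes the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM in the higher group, groups that do not overlap and a symbol that is not a predicted-gene, clone or ID name. For Vortex against HSS it takes 3 and 3. For each list called or described it takes the 3 members with the smallest p, and 16 genes of flow, endothelial, adhesion, mesenchymal and smooth muscle biology are given in every comparison. The text gives part of the genes that the rule takes. Other genes are said to be chosen after their values were seen.

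The procedure was tested on simulated data with 200 genes changed by 2-fold or 4-fold. With the spread of all 9 libraries, 5% to 11% of the 2-fold and 54% to 63% of the 4-fold changes were called in the 3 comparisons. With the spread found without Vortex replicate 2 these shares were 47% to 69% and 84% to 86%. All recovered changes had the right direction, and 1 to 11 genes were called falsely. The simulations gave each gene the same spread in all groups and held no outlying library. Their false calls therefore do not measure the error rate in these data, where the groups differ in spread.

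Alternatives planned before the data were examined were DESeq2 size factors or library totals in place of TMM, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, the replicate number as a block, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2 FPKM with a pseudocount of 1 or 0.1, a fit of the 6 compared libraries, a minimum change of 2-fold and leaving out each compared library. Added after the data were seen were leaving out the libraries of the third group, the removal of a smooth GC trend from each library as an offset (lowess span 0.3), that removal with Vortex replicate 2 left out, and list tests without Vortex replicate 2. GC content came from GENCODE release M21 on GRCm38, matched by gene identifier, which covered 98.5% of tested genes. No coordinates are given, since that build differs from the authors' build. Shared calls were set against 20 simulations of HSS and Vortex without a difference from PSS. Spread between replicates was compared with counting error by a chi-square per degree of freedom over genes with at least 20 counts.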

Results

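The transcriptome of bEnd.3 cells, a mouse brain endothelial line immortalised by the polyoma virus middle T antigen, was sequenced after exposure to flow on coverslips in a parallel-plate chamber. The 9 libraries form 3 groups of 3. PSS cells received laminar flow at 10 dyne/cm2, which the submitters set as the normal shear in brain vessels. HSS cells received laminar flow at 20 dyne/cm2, their model of the early aneurysm at a vessel bifurcation, and Vortex cells received vortex flow at 0.5 to 2 dyne/cm2, their model of the late, enlarged aneurysm. By its title the series asks whether flow drives a change of endothelial phenotype. Total counts per library were 18652837, 19287867 and 20785031 for PSS replicates 1, 2 and 3, 20778754, 17407217 and 18607119 for HSS, and 17445425, 22965802 and 20939381 for Vortex. Of 31232 genes listed, 15774 had enough counts to be tested.

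The HSS libraries lay close together and the Vortex libraries did not. Pearson correlations of log2 CPM (counts scaled to a common library total) across genes were 0.992 to 0.993 between HSS libraries, 0.977 to 0.992 between PSS libraries and 0.852 to 0.962 between Vortex libraries, where genes are not independent replicates. The lowest value was that of Vortex replicates 1 and 2. On a principal component map, the first component took 46.4% of the variance and set Vortex replicate 2 at -121.6, against 64.8 and 15.5 for Vortex replicates 1 and 3. Vortex replicate 2 had 30567 counts of Pecam1, an endothelial junction gene, where the other 8 libraries had 23 to 1116. Its counts also followed the GC content of genes. Relative to PSS, the median log2 difference was -1.47 in the eighth of genes with the lowest GC content and 0.88 in the eighth with the highest, and the next largest such pair was -0.48 and 0.26, in Vortex replicate 3. Values without Vortex replicate 2 are therefore also given for part of the gene groups. The p-values below rest on a spread per gene shared by all 9 libraries, not on that of the groups compared alone. Since the Vortex libraries differ most among themselves and the HSS ones least, p-values of Vortex comparisons can be too small. Fits of only the compared libraries called 74 genes for Vortex against PSS and 66 against HSS, where the main fit called 2107 and 1111. The spread can also be technical: nothing in the labels says that the replicates were separate cultures, and the extraction protocol speaks of mixed RNA.

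**Figure D1:**
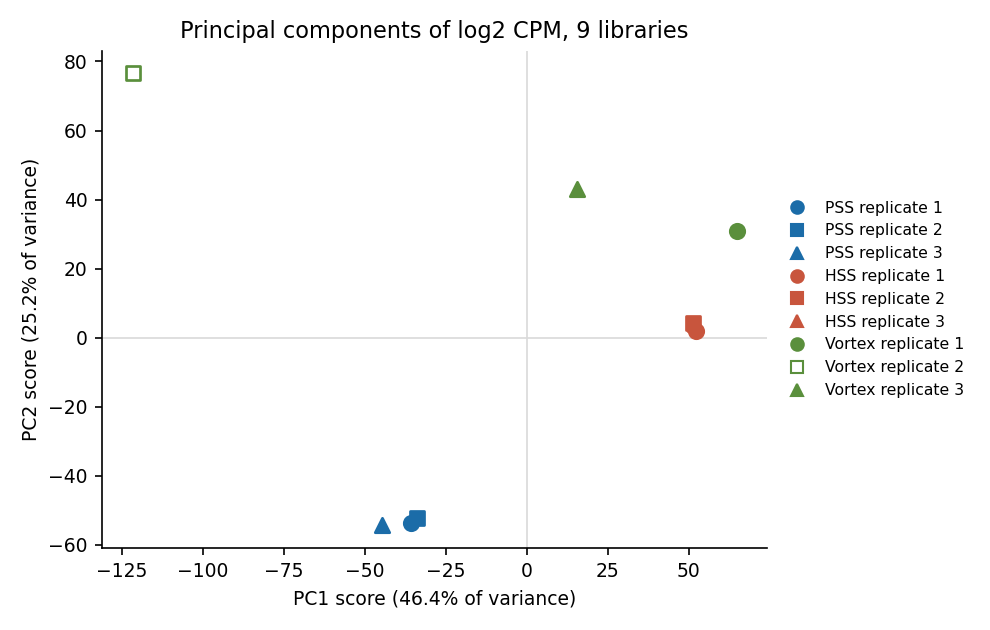
Principal components of log2 CPM for the 9 libraries, with each axis giving its share of variance (46.4% and 25.2%), colours for the flow groups and circle, square and triangle for replicates 1, 2 and 3. The 3 HSS libraries lie within 51.4 and 52.2 on the first component, and Vortex replicate 2 lies at -121.6.

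**Figure D2:**
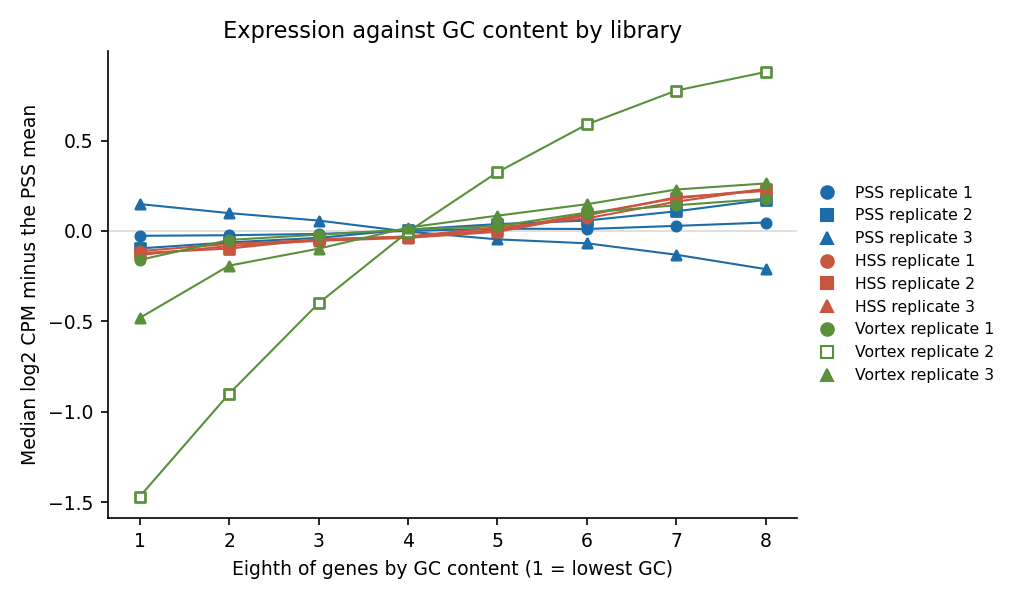
Median log2 difference from the PSS mean (vertical axis) in each of 8 equal groups of genes ordered by GC content (horizontal axis), with 1 line per library and flow groups by colour. The line of Vortex replicate 2 runs from -1.47 to 0.88, and those of the 3 HSS libraries end between 0.22 and 0.23.

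The comparison of HSS with PSS asks what a doubling of laminar shear, as at a bifurcation, does to these cells. Many of the genes that define endothelial cells were lower and many inflammatory genes higher. Kdr (ENSMUSG00000062960), the main receptor for vascular endothelial growth factor, was at 7.39 ± 0.315 CPM in HSS and 438 ± 35.9 in PSS (mean ± SD, n = 3 each), a log2 fold change of -5.89 ± 0.83 (SE). Idi1 (ENSMUSG00000058258), an isomerase of cholesterol synthesis, fell from 56.8 ± 10.9 to 8.34 ± 0.45 CPM (log2 fold change -2.77 ± 0.23). Ccl2 (ENSMUSG00000035385), a chemokine that attracts monocytes, rose from 16.0 ± 3.17 to 470 ± 22.9 CPM (log2 fold change 4.88 ± 0.49). The adjusted p-values of these genes were 0.0048, 0.00122 and 0.00158 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, which every adjusted p of a gene below also comes from.

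The list of endothelial identity genes had 29 tested members, with a median log2 fold change of -2.96. Of these, 14 fell, 0 rose and 15 did not pass, and adjusted over the list alone 21 fell and 1 rose (camera, adjusted p = 9.48e-15, and adjusted p = 0.352 with an estimated correlation). In a fit without Vortex replicate 2, whose spread enters this comparison, 25 were lower and 1 higher (camera adjusted p = 3.36e-28, and 0.136 with an estimated correlation). Vwf, which carries platelets to damaged vessel wall, fell by 5.65 on the log2 scale (SE 0.89), and Erg, a transcription factor of the endothelial lineage, by 7.07 (SE 1.38). Cdh5, the cadherin of endothelial junctions, had a log2 fold change of -2.11 ± 0.47, and Nos3, the endothelial nitric oxide synthase, of -3.26 ± 0.76 (adjusted p = 0.0296 and 0.0332). Cldn5, the tight junction claudin of brain endothelium, had 3474 counts in PSS and 2 in HSS, a ratio of 1641 with a 95% counting interval of 454 to 13554. Such intervals, and the floors of 3 counts used where a group had none, cover counting error only. Without any 1 of the PSS or HSS libraries the calls of Erg, Cdh5, Nos3 and Cldn5 ended (adjusted p up to 0.0936, 0.126, 0.145 and 0.207), and that of Vwf ended without HSS replicate 2 or 3 (0.0518 and 0.0508). With Vortex replicate 2 left out the adjusted p of Erg, Cdh5, Nos3, Cldn5 and Vwf was 0.000151, 3.09e-06, 7.11e-06, 1.77e-06 and 4.21e-06. Pecam1 (-3.22 ± 1.65, adjusted p = 0.285) did not pass with all libraries and passed without Vortex replicate 2 (0.023). Klf2, a transcription factor induced by laminar flow, was at -2.91 ± 0.78 with adjusted p = 0.054, and passed without Vortex replicate 1, 2 or 3 (0.0158, 4.24e-06 and 0.0486). Klf4, its relative, was at -0.34 ± 0.33 (adjusted p = 0.605).

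Related lists were lower too. In the Notch pathway list, 5 of 24 members fell, 0 rose and 19 did not pass, with 9 lower and 1 higher adjusted over the list alone (median -1.12, adjusted p = 6.85e-05, and adjusted p = 0.408 with an estimated correlation). Its ligand gene Dll1 fell by 3.68 on the log2 scale (SE 0.53). With Vortex replicate 2 left out the Notch list had 15 of 23 lower and 2 higher (median -1.10, camera adjusted p = 4.14e-08, and 0.205 with an estimated correlation). The laminar flow response list had 4 of 20 members lower and 2 higher, and 8 lower and 3 higher adjusted over the list alone (median -0.98, adjusted p = 0.0218, and adjusted p = 0.193 with an estimated correlation). The disturbed flow response list had 4 of 20 lower and 0 higher, with 5 lower adjusted over the list alone (median -0.17). It passed by fry (adjusted p = 0.00304) but not by camera (adjusted p = 0.0788). Among the list of angiogenic growth factors and tip cell genes, 5 of 28 fell and 1 rose, with 7 lower and 4 higher adjusted over the list alone (median -0.61, adjusted p = 0.0218, and adjusted p = 0.316 with an estimated correlation). Calcrl, a receptor for adrenomedullin, fell by 1.69 (SE 0.24).

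Cholesterol synthesis was the list with the smallest p. Of its 25 members, 19 fell, 0 rose and 6 did not pass, and 22 were lower adjusted over the list alone (median -1.51, adjusted p = 7.1e-28, and adjusted p = 0.00506 with an estimated correlation). Cyp51, the lanosterol demethylase, fell by 2.60 on the log2 scale (SE 0.24) and Fdft1, squalene synthase, by 2.10 (SE 0.21). Both had adjusted p-values under 0.05 without each of the 9 libraries in turn, as did Idi1.

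Inflammatory lists were higher. Of 30 genes for leukocyte adhesion and chemokines, 14 rose, 0 fell and 16 did not pass, and 20 were higher adjusted over the list alone (median 1.41, adjusted p = 1.53e-15, and adjusted p = 0.193 with an estimated correlation). In a fit without Vortex replicate 2, 23 were higher and 0 lower (camera adjusted p = 4.57e-22, and 0.0289 with an estimated correlation). Ccl20, a chemokine for lymphocytes and dendritic cells, rose by a log2 fold change of 5.37 ± 0.73, and Csf1, the growth factor of macrophages, by 2.28 ± 0.28. The interferon response list had 15 of 33 members higher, 0 lower and 18 not passing, and 29 higher adjusted over the list alone (median 1.60, adjusted p = 9.12e-20, and adjusted p = 0.193 with an estimated correlation). With Vortex replicate 2 left out, 32 were higher and 0 lower (camera adjusted p = 8.07e-37, and 0.0289 with an estimated correlation). Zbp1, a sensor of nucleic acids induced by interferon, was at 6.32 ± 1.01. In the antigen presentation list, 7 of 17 members rose, 0 fell and 10 did not pass, with 9 higher and 1 lower adjusted over the list alone (median 1.36, adjusted p = 4.96e-08, and adjusted p = 0.0145 with an estimated correlation). Tap1, a transporter that loads peptides for class I molecules, was at 1.64 ± 0.17, and H2-D1, a class I gene whose reads can be shared with close relatives, at 1.87 ± 0.21. Macrophage and leukocyte markers had 2 of 11 members higher and 1 lower, with 4 higher and 2 lower adjusted over the list alone (median 1.19, adjusted p = 0.0491, and adjusted p = 0.352 with an estimated correlation). Csf1r, the receptor for Csf1, was at 3.20 ± 0.37. That list did not pass without any 1 of the PSS or HSS libraries or Vortex replicate 1 or 2 (adjusted p = 0.124, 0.163 and 0.146 for PSS replicates 1, 2 and 3, 0.0818, 0.0932 and 0.115 for HSS, and 0.317 and 0.0664 for Vortex), and its median in those settings was 0.30 to 0.97. It also did not pass with the GC trend removed (median 1.18, adjusted p = 0.0564). The adhesion genes Vcam1 (0.55 ± 0.52, adjusted p = 0.594) and Icam1 (-0.32 ± 0.36, adjusted p = 0.662) did not pass, although Vcam1 passed without Vortex replicate 2 (0.0147).

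Of the genes with the largest change, Nos2, the inducible nitric oxide synthase, had 7 counts in PSS and 14219 in HSS (0.112 ± 0.0992 and 245 ± 8.93 CPM). Saa3, an acute phase protein with close paralogs, was at 8.44 ± 1.75, and Fyb1, an adaptor of immune cell signalling, at 7.43 ± 1.32. Vnn3 and Serpina3n had 0 counts in PSS and were at least 127-fold and 104-fold higher in HSS against a floor of 3 counts over the group. Among the largest falls, besides Cldn5 and Erg, was that of Mgp, a matrix protein that limits calcification (409 counts in PSS against 1 in HSS, ratio 386 with interval 69.0 to 15297). The calls of Saa3, Vnn3 and Serpina3n ended without any 1 PSS or HSS library (adjusted p up to 0.111, 0.133 and 0.141), and those of Vnn3 and Serpina3n also without Vortex replicate 3 (0.0706 and 0.074). That of Fyb1 ended without any 1 PSS library (up to 0.0765), and that of Nos2 without PSS replicate 1 or 3 (0.0508 and 0.056).

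Further metabolic and stress lists were called. In the glycolysis and hypoxia list 6 of 30 members rose and 0 fell, with 13 higher adjusted over the list alone (median 0.58, adjusted p = 4.59e-06, and adjusted p = 0.249 with an estimated correlation), and P4ha2, a collagen prolyl hydroxylase, was at 1.75 ± 0.24. In the NRF2 and oxidative stress list 7 of 27 rose and 0 fell, with the same counts adjusted over the list alone (median 0.34, adjusted p = 0.000521, and adjusted p = 0.193 with an estimated correlation), and Srxn1, which repairs oxidised peroxiredoxins, was at 1.27 ± 0.20. Immediate early genes had 5 of 28 higher and 1 lower, with 8 higher and 1 lower adjusted over the list alone (median 0.53, adjusted p = 0.00249, and adjusted p = 0.352 with an estimated correlation). Of 73 ribosomal protein genes 1 fell, 0 rose and 72 did not pass, with 44 lower adjusted over the list alone (median -0.64, adjusted p = 3.04e-12, and adjusted p = 0.491 with an estimated correlation). The medians of that list in single PSS libraries ran from -0.38 to 0.51 around their own mean. With Vortex replicate 2 left out 46 of the 73 were lower and 0 higher (camera adjusted p = 1.95e-07, and 0.702 with an estimated correlation). Lists with weaker p were matrix proteases and inhibitors (median 0.48, 5 of 30 higher and 1 lower, 6 and 4 adjusted over the list alone, adjusted p = 0.0376, and adjusted p = 0.573 with an estimated correlation), oxidative phosphorylation (median -0.33, 0 of 32 passing by edgeR over all genes or adjusted over the list alone and 7 at an unadjusted p under 0.05, camera adjusted p = 0.0376, and adjusted p = 0.811 with an estimated correlation) and neural and glial markers (median -0.30, 2 of 12 lower, 2 adjusted over the list alone, adjusted p = 0.0218, and adjusted p = 0.193 with an estimated correlation). The protease call ended without PSS replicate 3 or Vortex replicate 1 (adjusted p = 0.126 and 0.0707). The oxidative phosphorylation call ended without PSS replicate 3, HSS replicate 3 or Vortex replicate 1, 2 or 3 (0.443, 0.0544, 0.0707, 0.0891 and 0.0535) and with the GC trend removed (0.0546), and its median was -0.07 without PSS replicate 3. The neural and glial call ended without PSS replicate 1, 2 or 3, HSS replicate 3 or Vortex replicate 1, 2 or 3 (0.108, 0.106, 0.0982, 0.122, 0.0688, 0.163 and 0.0679).

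Mesenchymal markers and smooth muscle genes did not pass as lists in HSS. Among 23 mesenchymal markers 2 fell, 0 rose and 21 did not pass, with the same counts adjusted over the list alone (median -0.04, camera adjusted p = 0.759). Snai2, a repressor of epithelial genes in mesenchymal transition, fell by 2.00 on the log2 scale (SE 0.52, adjusted p = 0.0479), and Postn, a matrix protein of fibroblasts, by 2.38 (SE 0.60, adjusted p = 0.0436). Both calls ended without any 1 PSS or HSS library or Vortex replicate 3 (adjusted p up to 0.196 and 0.176). Snai1, a relative of Snai2, was at 0.86 ± 0.27 (adjusted p = 0.0859) and passed without Vortex replicate 1 or 2 (0.0356 and 0.00244). Fn1, fibronectin, was at 0.49 ± 0.25 (adjusted p = 0.287). Of 12 smooth muscle contractile genes 0 passed by edgeR over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (median 0.10, camera adjusted p = 0.896). Acta2, smooth muscle actin, was at 0.838 ± 0.469 CPM in HSS and 1.22 ± 0.18 in PSS (log2 fold change -0.53 ± 0.49, adjusted p = 0.58). Tagln, another contractile gene, had 0 to 5 counts in each of the 9 libraries and was not tested. Mmp9, a gelatinase, was at 3.38 ± 0.83 (adjusted p = 0.0406), a call that ended without any 1 PSS or HSS library or Vortex replicate 3 (up to 0.161). Edn1, the vasoconstrictor endothelin, was at -1.82 ± 0.81 (adjusted p = 0.217) and passed without Vortex replicate 2 (2.59e-05).

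Over all genes, 1242 differed between HSS and PSS, 659 higher and 583 lower in HSS, of which 1008 changed by at least 2-fold. The HSS and PSS ranges did not overlap for 8866 genes (56.2%), where chance gives 10% on average. Genes move together, so a single grouping can lie far from that average, and the share is not a test. The count was 314, 462 and 505 without PSS replicate 1, 2 and 3, and 296, 301 and 285 without HSS replicate 1, 2 and 3. It was 2011 without Vortex replicate 1 and 4730 (2501 higher and 2229 lower) without Vortex replicate 2, with the spread of each gene estimated over all libraries of the fit. A fit of only the PSS and HSS libraries called 6233 genes. Of the 36 lists tested, 16 passed with the preset correlation and 2 with an estimated one, cholesterol synthesis and antigen presentation. By fry 10 lists passed. Of the 16 it did not call endothelial identity (adjusted p = 0.0622), ribosomal proteins (0.0796), Notch (0.0865), immediate early genes (0.0514), angiogenic genes (0.0531), matrix proteases (0.146), oxidative phosphorylation (0.31) and macrophage and leukocyte markers (0.0622). Fry alone called the disturbed flow response lower (0.00304) and p53 and senescence higher (0.00737). Leaving out Vortex replicate 2, 14 lists passed with the preset correlation and 6 of them with an estimated one as well, among them the interferon list (adjusted p = 0.0289) and the leukocyte adhesion and chemokine list (0.0289).

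**Figure D3:**
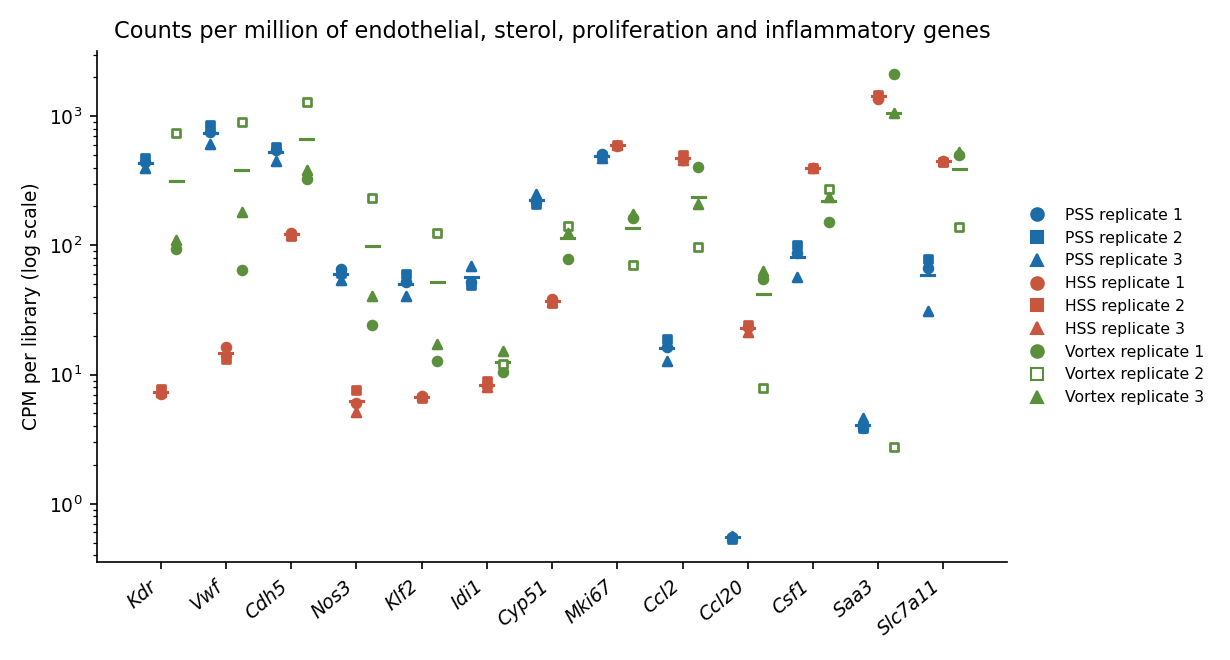
CPM on a log axis (vertical) of 13 named genes in the 9 libraries, with 1 point per library, bars for group means, colours for flow groups and circle, square and triangle for replicates 1, 2 and 3. Kdr lies near 7.39 CPM in HSS and 438 in PSS, and the open square of Vortex replicate 2 stands apart from the other Vortex libraries for the endothelial genes.

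The comparison of Vortex with PSS asks how slow, disturbed flow, as in an enlarged aneurysm, differs from normal laminar flow. Lists of inflammatory, antioxidant, hypoxic and lysosomal genes were called higher, and those of cholesterol synthesis and cell cycle genes lower, each with a part of its genes passing. With an estimated correlation only the antigen presentation list passed. Ccl20 rose from 0.553 ± 0.0168 CPM in PSS to 41.8 ± 29.7 in Vortex (n = 3 each, log2 fold change 6.22 ± 0.75, adjusted p = 0.00319), and Ccl2 from 16.0 ± 3.17 to 235 ± 154 (3.88 ± 0.47, adjusted p = 0.00319). Idi1 fell from 56.8 ± 10.9 to 12.6 ± 2.43 CPM (log2 fold change -2.17 ± 0.22, adjusted p = 0.0022). Mki67, a gene of proliferating cells, fell from 491 ± 14.7 to 136 ± 56.5 CPM (-1.86 ± 0.30, adjusted p = 0.00703).

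Of the 30 leukocyte adhesion and chemokine genes 20 rose, 0 fell and 10 did not pass, and 24 were higher adjusted over the list alone (median 2.31, adjusted p = 2.73e-15, and adjusted p = 0.164 with an estimated correlation). Selp, which slows leukocytes on the vessel wall, was at 3.01 ± 0.38. Vcam1 was at 1.56 ± 0.53 (adjusted p = 0.0807) and passed without Vortex replicate 2 (2.03, adjusted p = 1.25e-05), and Icam1 was at 0.80 ± 0.36 (adjusted p = 0.173) and passed without Vortex replicate 1 (0.0466). In the antigen presentation list 9 of 17 rose and 0 fell, with 12 higher adjusted over the list alone (median 1.42, adjusted p = 1.55e-09, and adjusted p = 0.0153 with an estimated correlation). H2-D1 was at 2.51 ± 0.22 and Tap1 at 1.42 ± 0.17. The interferon response list had 6 of 33 members higher and 0 lower, with 11 higher adjusted over the list alone (median 0.62, adjusted p = 0.00442, and adjusted p = 0.677 with an estimated correlation). Its median was 0.84 and 0.97 in Vortex replicates 1 and 3 and -0.63 in Vortex replicate 2, and the call ended without Vortex replicate 3 (adjusted p = 0.234). Leaving out Vortex replicate 2, 23 members were higher and 0 lower (median 0.86, adjusted p = 1.66e-11, and adjusted p = 0.122 with an estimated correlation). Macrophage and leukocyte markers had 4 of 11 members higher and 0 lower, with 8 higher adjusted over the list alone (median 2.19, adjusted p = 0.000126, and adjusted p = 0.164 with an estimated correlation). They included Csf1r, the receptor for Csf1, at 2.78 ± 0.36, and Cd68, a lysosomal glycoprotein of macrophages, at 2.53 ± 0.49, whose call ended without any 1 PSS library (adjusted p up to 0.0621).

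Stress and degradation lists were higher. In the NRF2 and oxidative stress list 11 of 27 rose and 0 fell, with 13 higher adjusted over the list alone (median 0.78, adjusted p = 3.2e-08, and adjusted p = 0.0856 with an estimated correlation). Its median was 0.44 without Vortex replicate 2, with 14 higher and 0 lower (adjusted p = 1.73e-06, and adjusted p = 0.0167 with an estimated correlation). Gstm1, a glutathione transferase, was at 1.66 ± 0.17 and Fth1, the heavy chain of ferritin, at 1.63 ± 0.22. In the glycolysis and hypoxia list 13 of 30 rose and 0 fell, with 17 higher adjusted over the list alone (median 0.77, adjusted p = 5.08e-08, and adjusted p = 0.164 with an estimated correlation), among them P4ha2 at 1.79 ± 0.24 and Ndrg1, a gene induced by hypoxia, at 2.67 ± 0.44. In the autophagy and lysosome list 13 of 30 rose and 0 fell, with 17 higher adjusted over the list alone (median 0.63, adjusted p = 1.28e-05, and adjusted p = 0.107 with an estimated correlation), with the lysosomal enzyme gene Hexa at 1.15 ± 0.16. The unfolded protein response list had 10 of 28 higher and 0 lower, with 12 higher adjusted over the list alone (median 0.62, adjusted p = 3.53e-05, and adjusted p = 0.368 with an estimated correlation). Trib3 and Chac1, targets of the stress factors ATF4 and CHOP, were at 2.90 ± 0.33 and 3.46 ± 0.54. The cell death list had 8 of 30 higher and 1 lower, with the same counts adjusted over the list alone (median 0.50, adjusted p = 0.0182, and adjusted p = 0.164 with an estimated correlation), a call that ended without Vortex replicate 1 (adjusted p = 0.0866). Gsdmd, which forms pores in pyroptosis, was at 1.41 ± 0.22, and Bcl2l1, which restrains apoptosis, at 1.25 ± 0.20.

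Matrix proteases and their inhibitors moved both ways. Of 30, 11 rose, 2 fell and 17 did not pass, with 13 higher and 2 lower adjusted over the list alone (median 0.96, adjusted p = 0.00231, and adjusted p = 0.415 with an estimated correlation). Adamts4, an aggrecanase, was at 2.16 ± 0.35 and Plaur, the urokinase receptor, at 1.58 ± 0.25, while Timp3, an inhibitor of metalloproteinases, fell by 1.34 on the log2 scale (SE 0.21). Mmp9 was at 3.05 ± 0.82 (adjusted p = 0.0408), a call that ended without any 1 PSS or HSS library or Vortex replicate 1 or 3 (up to 0.149).

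In the cholesterol synthesis list 6 of 25 fell and 0 rose, with 11 lower adjusted over the list alone (median -0.54, adjusted p = 3.53e-05, and adjusted p = 0.125 with an estimated correlation), and Hmgcs1, an early enzyme of the pathway, fell by 1.32 on the log2 scale (SE 0.21). There were 18 lower and 1 higher without Vortex replicate 2 (median -0.64, adjusted p = 1.07e-05, and adjusted p = 0.0552 with an estimated correlation). In the cell cycle list 7 of 40 fell and 0 rose, with 7 lower adjusted over the list alone (median -0.38, adjusted p = 0.000194, and adjusted p = 0.656 with an estimated correlation). Kif11, a mitotic motor, fell by 1.71 (SE 0.28). The cell cycle medians were -1.11, 0.26 and -0.45 in Vortex replicates 1, 2 and 3. The call ended without Vortex replicate 1 (adjusted p = 0.175), and without Vortex replicate 2 the list had 29 members lower (median -0.74, adjusted p = 7.67e-09, and adjusted p = 0.439 with an estimated correlation). Of 73 ribosomal protein genes 0 passed by edgeR over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 (median 0.28, camera adjusted p = 0.00308, and adjusted p = 0.771 with an estimated correlation), and the call ended without PSS replicate 2 or Vortex replicate 2 (0.273 and 0.0712) and with the GC trend removed (median 0.19, adjusted p = 0.0656).

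Endothelial identity genes did not pass as a list between Vortex and PSS, and the Vortex libraries went both ways. The list median relative to PSS was -1.67, 1.31 and -0.55 in Vortex replicates 1, 2 and 3, and the fitted median was 0.27 with 1 of 29 members higher and 0 lower, over all genes and over the list alone (adjusted p = 0.54). Without Vortex replicate 2 the median was -1.09, with 22 members lower and 1 higher (adjusted p = 2.09e-07, and adjusted p = 0.439 with an estimated correlation). The gene that rose was Flt1, a decoy receptor for vascular endothelial growth factor, at 1.01 ± 0.18. Klf2 (0.03 ± 0.72, adjusted p = 0.982), Nos3 (0.73 ± 0.69, 0.527), Cdh5 (0.35 ± 0.46, 0.658), Cldn5 (1.14 ± 1.52, 0.664) and Edn1 (-0.05 ± 0.78, 0.972) did not pass. Without Vortex replicate 2 they were at -1.75, -0.88, -0.57, -4.81 and -2.13, with adjusted p = 0.000204, 0.016, 0.0119, 3.78e-05 and 3.27e-05. Pecam1 was at 5.22 ± 1.71 (adjusted p = 0.074), passed without Vortex replicate 1 (0.0112) and was at 1.09 without Vortex replicate 2 (0.33). Klf4 was at -0.26 ± 0.33 (adjusted p = 0.652). Neither flow response list passed by camera. The disturbed flow list had 4 of 20 higher and 3 lower, with 5 and 3 adjusted over the list alone (median 0.43, adjusted p = 0.712). The laminar flow list had 2 of 20 higher and 4 lower, with 3 and 4 adjusted over the list alone (median 0.39, adjusted p = 0.784). The laminar median was -0.49 without Vortex replicate 2 (camera adjusted p = 0.159), and the disturbed one 0.40 (0.95). The Notch pathway list had a median of 0.44 with all libraries (0 of 24 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.571) and -0.99 without Vortex replicate 2 (12 of 23 lower and 2 higher, adjusted p = 0.000514, and adjusted p = 0.439 with an estimated correlation). The median with all libraries turned to -0.08 when the GC trend was removed.

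**Figure D4:**
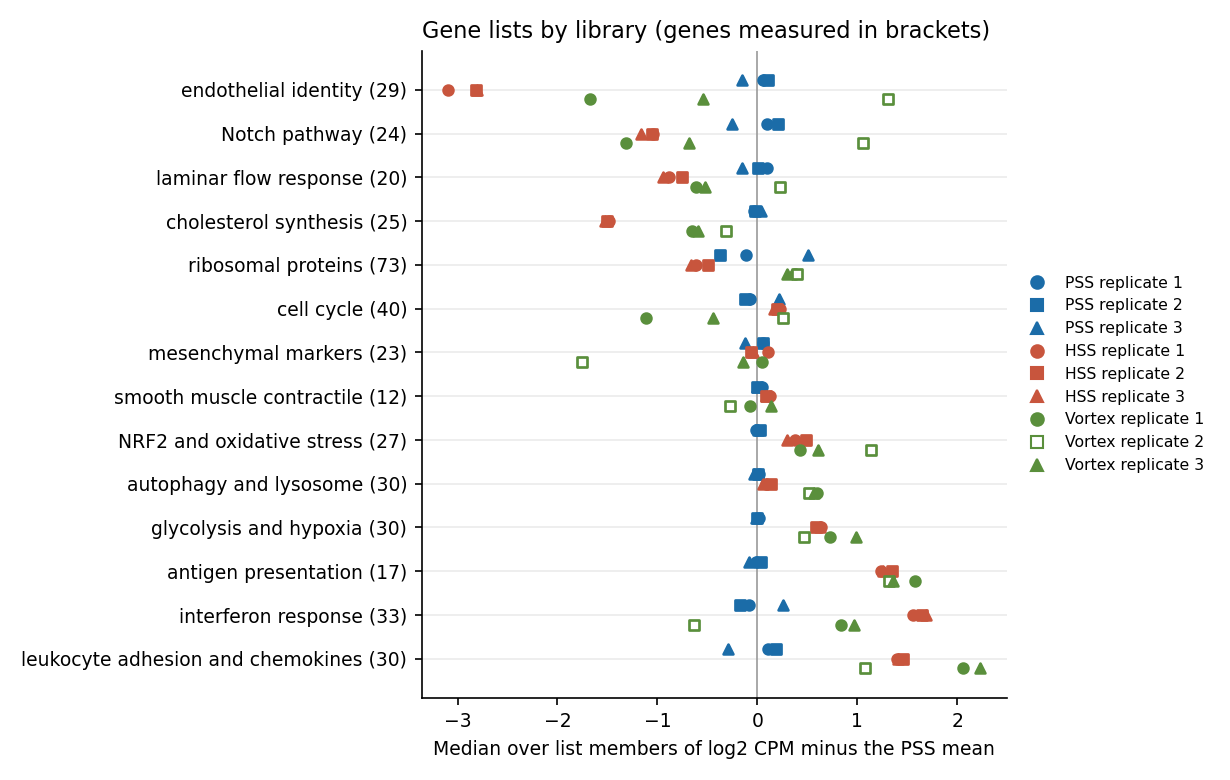
Median log2 difference from the PSS mean (horizontal axis) over the tested members of 14 gene lists, with the number of members in brackets, 1 point per library, colours for flow groups and circle, square and triangle for replicates 1, 2 and 3. The endothelial identity medians were -3.09 to -2.81 in HSS, -1.67 and -0.55 in Vortex replicates 1 and 3, and 1.31 in Vortex replicate 2.

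Mesenchymal markers moved both ways in Vortex. Of 23, 2 rose, 2 fell and 19 did not pass, with the same counts adjusted over the list alone (median -0.26, adjusted p = 0.218). Their median was -1.76 in Vortex replicate 2, and 0.05 and -0.14 in Vortex replicates 1 and 3. In a fit without Vortex replicate 2, 8 of 24 were higher and 4 lower (median -0.00089, camera adjusted p = 0.324). Snai1 was at 1.36 ± 0.27 (adjusted p = 0.0126), a call that ended without PSS replicate 1 or 2 (0.0722 and 0.0507). Postn fell by 3.36 on the log2 scale (SE 0.66) and Cdh2, the neural cadherin, by 0.73 (SE 0.18), calls that ended without PSS replicate 1 (0.0632) and without any 1 PSS or HSS library (up to 0.117). Snai2 (-0.26 ± 0.49, adjusted p = 0.768) and Fn1 (0.06 ± 0.25, adjusted p = 0.902) did not pass, and Snai2 passed without Vortex replicate 2 (-1.01, adjusted p = 0.04). Of 12 smooth muscle contractile genes 0 rose and 2 fell, over all genes and adjusted over the list alone (median 0.50, adjusted p = 0.54). Those were Synpo2 and Cald1, which bind actin, lower by -3.51 ± 0.44 and -1.10 ± 0.19. The smooth muscle list had 4 higher and 3 lower without Vortex replicate 2 (median -0.06, camera adjusted p = 0.72). Acta2 was at 0.58 ± 0.213 CPM in Vortex (log2 fold change -1.07 ± 0.50, adjusted p = 0.188). Pericyte and fibroblast markers had 2 of 17 higher and 3 lower, the same adjusted over the list alone (median -0.56, adjusted p = 0.0278, and adjusted p = 0.677 with an estimated correlation). The call ended without PSS replicate 2 (0.0593) or with scaling to library totals (0.0584). The test pointed upward (0.72) without Vortex replicate 2, whose own median was -2.11.

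Of the genes with the largest rise, Nos2 was at 9.88 ± 1.73, Fgf23, a hormone of phosphate balance, at 8.30 ± 1.68, and Fyb1 at 6.35 ± 1.29. Serpina3n had 0 counts in PSS and was at least 91.5-fold higher in Vortex. These rises were mostly those of Vortex replicates 1 and 3. Counts in Vortex replicates 1, 2 and 3 were 2442, 29 and 3707 for Nos2, 889, 6 and 2094 for Fgf23, 206, 7 and 408 for Fyb1 and 197, 2 and 56 for Serpina3n. Among the largest falls were those of Mgp (-5.48 ± 0.82), Gkn3 (-4.96 ± 0.43), Capn6 (-4.08 ± 0.70) and Sema3d, a guidance cue (-3.63 ± 0.36). The calls of Fgf23 and Fyb1 ended without any 1 PSS library (adjusted p up to 0.0757 and 0.0754), that of Nos2 without PSS replicate 1 (0.0514), and that of Serpina3n without any 1 PSS or HSS library or Vortex replicate 3 (up to 0.101).

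Over all genes, 2107 differed between Vortex and PSS, 1314 higher and 793 lower (62.4% higher), and 1447 changed by at least 2-fold. A fit of only the PSS and Vortex libraries called 74 genes. The main fit also draws the spread of each gene from the HSS libraries, which lay closest together. The group ranges did not overlap for 4728 genes (30.0%), where chance gives 10% on average, again not a test. The split depended on the scaling. With library totals it was 835 higher and 1165 lower (41.8% higher), with limma on log2 FPKM 33.4% and 35.1% were higher for pseudocounts of 1 and 0.1, and with the GC trend removed 1203 were higher and 449 lower (72.8%). The median log2 fold change of all tested genes was 0.11 with the main scaling and -0.06 with library totals, and 0.10 and -0.03 for Vortex against HSS. The count was 519, 910 and 1074 without PSS replicate 1, 2 and 3, 1112, 1115 and 1116 without HSS replicate 1, 2 and 3, and 5888 (3190 higher and 2698 lower) without Vortex replicate 2. Of 36 lists 14 passed with the preset correlation and 1 with an estimated one, antigen presentation. Fry called 12 lists, and of the 14 not cell cycle (adjusted p = 0.154), matrix proteases (0.0658), ribosomal proteins (0.233), interferon response (0.228) and pericyte and fibroblast markers (0.207). Fry alone called p53 and senescence (0.000578) and blood-brain barrier (0.0086) higher and neural and glial markers (0.00418) lower. Without Vortex replicate 2, 18 passed with the preset correlation and 5 of them with both. Of these 18, the lists that did not pass by camera with all libraries were endothelial identity, Notch, TGF-beta and BMP response (median -0.84, 15 of 23 lower and 2 higher, adjusted p = 0.00155), Wnt (0.0297), immediate early genes (0.0301) and p53 and senescence (0.0224). With an estimated correlation their adjusted p ran from 0.183 to 0.562.

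The comparison of Vortex with HSS sets the models of the late and the early aneurysm against each other. Lists of ribosomal, endothelial identity and cholesterol synthesis genes were called higher in Vortex, and interferon and cell cycle lists lower, each with a part of its genes passing. With an estimated correlation 0 of the 36 lists passed. Sfrp2, a secreted Wnt modulator, fell from 94.0 ± 2.71 CPM in HSS to 9.05 ± 3.34 in Vortex (n = 3 each, log2 fold change -3.38 ± 0.29, adjusted p = 0.00258). Itga2, a collagen receptor subunit, was at 3.04 ± 0.23 (adjusted p = 0.00211). Srebf2, the main activator of cholesterol synthesis genes, was at 1.91 ± 0.22 (94.5 ± 3.28 CPM in HSS, 355 ± 81.2 in Vortex). Without any 1 HSS library, the calls of 77 of the 81 genes named by rule in this comparison ended, and those of Sfrp2 and Itga2 did not.

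Of 73 ribosomal protein genes 31 rose, 0 fell and 42 did not pass, and 71 were higher adjusted over the list alone (median 0.92, adjusted p = 8.02e-27, and adjusted p = 0.372 with an estimated correlation). Rpl8, Rpl28 and Rps15 were at 0.89 ± 0.17, 1.10 ± 0.21 and 1.10 ± 0.23. In the cholesterol synthesis list 10 of 25 rose and 0 fell, with 17 higher adjusted over the list alone (median 0.75, adjusted p = 9.18e-11, and adjusted p = 0.0899 with an estimated correlation), with Fdft1 at 1.54 ± 0.20 and Cyp51 at 1.63 ± 0.23. In the autophagy and lysosome list 8 of 30 rose and 0 fell, with 10 higher and 1 lower adjusted over the list alone (median 0.50, adjusted p = 1.38e-05, and adjusted p = 0.168 with an estimated correlation), and Ctsd, a lysosomal protease, was at 1.41 ± 0.18. The unfolded protein response list had 6 of 28 higher and 0 lower, with 9 higher adjusted over the list alone (median 0.50, adjusted p = 0.000382, and adjusted p = 0.441 with an estimated correlation), and Atf4, the stress transcription factor, was at 1.10 ± 0.14. Its list call ended without Vortex replicate 1, at an adjusted p just above 0.05. The oxidative phosphorylation list had 2 of 32 higher and 0 lower, with 4 higher adjusted over the list alone (median 0.46, adjusted p = 9.17e-05, and adjusted p = 0.551 with an estimated correlation). The calls of Rpl8, Rpl28, Rps15, Fdft1, Cyp51, Ctsd and Atf4 ended without any 1 HSS library (adjusted p up to 0.128, 0.123, 0.143, 0.0808, 0.0823, 0.0781 and 0.0817), those of the 3 ribosomal genes also without PSS replicate 1 (0.0542, 0.0544 and 0.0608), and that of Rps15 without Vortex replicate 3 (0.0616).

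Of 29 endothelial identity genes 14 rose, 0 fell and 15 did not pass, and 25 were higher adjusted over the list alone (median 3.36, adjusted p = 4.57e-11, and adjusted p = 0.441 with an estimated correlation). The median was 1.63 without Vortex replicate 2, with 19 higher and 0 lower (adjusted p = 3.04e-12, and adjusted p = 0.264 with an estimated correlation). Kdr was at 5.42 ± 0.81, Vwf at 4.70 ± 0.85, Cdh5 at 2.46 ± 0.48 and Nos3 at 3.99 ± 0.78, and without Vortex replicate 2 they were at 3.78, 3.06, 1.54 and 2.38. Pecam1 was at 8.44 ± 2.01, and at 4.31 without Vortex replicate 2, where Cldn5 was at 5.63 and Chrm3 at 4.31. Cldn5 had 2 counts in HSS and 7866 in Vortex, 7791 of them in Vortex replicate 2, a ratio of 3999 with a 95% counting interval of 1107 to 33024. Chrm3, a muscarinic receptor, had 3 counts in HSS and 952 in Vortex (ratio 323, interval 110 to 1567). Klf2 was at 2.94 ± 0.78 (adjusted p = 0.0536) and passed without Vortex replicate 1, 2 or 3 (0.0152, 0.00374 and 0.0424), with a value of 1.16 without Vortex replicate 2. The calls of Kdr, Vwf, Cdh5, Nos3, Pecam1, Cldn5 and Chrm3 ended without any 1 HSS library (adjusted p up to 0.0843, 0.109, 0.123, 0.126, 0.175, 0.187 and 0.158). Those of Cdh5 and Nos3 also ended without PSS replicate 1 (0.0544 and 0.0541), and those of Pecam1, Cldn5 and Chrm3 without any 1 PSS library (up to 0.0791, 0.0778 and 0.0707). The Notch pathway list had 3 of 24 higher and 1 lower, with 11 higher and 1 lower adjusted over the list alone (median 1.95, adjusted p = 0.00224, and adjusted p = 0.551 with an estimated correlation), and it did not pass without Vortex replicate 2 (median 0.35, 7 of 23 higher and 2 lower, adjusted p = 0.0707). The blood-brain barrier list had 6 of 29 higher and 1 lower, with 10 higher and 2 lower adjusted over the list alone (median 0.43, adjusted p = 0.00742, and adjusted p = 0.259 with an estimated correlation). Ocln, a tight junction protein, was at 1.51 ± 0.22, a call that ended without any 1 HSS library (up to 0.0843).

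The 2 lists of flow responses were both higher in Vortex than in HSS, while neither passed in Vortex against PSS (camera adjusted p = 0.712 for disturbed and 0.784 for laminar flow). In the disturbed flow list 6 of 20 rose and 1 fell, with 8 higher and 2 lower adjusted over the list alone (median 0.93, adjusted p = 0.021, and adjusted p = 0.259 with an estimated correlation). Sele and Selp, selectins of activated endothelium named for the leukocyte adhesion and chemokine list, were at 3.80 ± 0.56 and 3.14 ± 0.38. Both calls ended without any 1 HSS library (adjusted p up to 0.0843 and 0.0781). The leukocyte adhesion and chemokine list did not pass as a whole with all libraries (median 0.12, camera adjusted p = 0.541). In the laminar flow list 2 of 20 rose and 1 fell, with 10 higher and 1 lower adjusted over the list alone (median 1.08, adjusted p = 0.042, and adjusted p = 0.372 with an estimated correlation), a call that ended without PSS replicate 3 or Vortex replicate 3 (0.081 and 0.0506) and with the GC trend removed (0.0806). This list had 8 of 19 higher and 2 lower without Vortex replicate 2 (median 0.82, camera adjusted p = 0.0241, and 0.236 with an estimated correlation). Vcam1 (1.02 ± 0.52, adjusted p = 0.248), Icam1 (1.12 ± 0.36, 0.0909), Ccl2 (235 ± 154 CPM in Vortex, 470 ± 22.9 in HSS, 0.168) and Klf4 (0.08 ± 0.33, 0.904) did not pass. Vcam1 passed without Vortex replicate 2 (0.000304), and Icam1 and Ccl2 without Vortex replicate 1 (0.0226 and 0.0197).

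Further lists were called with larger p. Angiogenic growth factors and tip cell genes had 8 of 28 higher and 1 lower, with 12 higher and 3 lower adjusted over the list alone (median 0.81, adjusted p = 0.0172, and adjusted p = 0.372 with an estimated correlation). Their median was 0.38 without Vortex replicate 2 (11 higher and 4 lower, adjusted p = 0.0241, and adjusted p = 0.428 with an estimated correlation). The NRF2 and oxidative stress list had 4 of 27 higher and 0 lower, with 7 higher adjusted over the list alone (median 0.41, adjusted p = 0.02, and adjusted p = 0.372 with an estimated correlation), and did not pass without Vortex replicate 2 (median 0.21, adjusted p = 0.0993). With the GC trend removed neither passed (0.0915 and 0.0968). Actin cytoskeleton and focal adhesion genes had 1 of 35 higher and 0 lower, the same adjusted over the list alone (median 0.32, adjusted p = 0.0204, and adjusted p = 0.443 with an estimated correlation), and did not pass without Vortex replicate 2 (median 0.07, adjusted p = 0.25). Of 11 replication-dependent histone genes, whose messages mostly lack a polyA tail, 0 passed by edgeR over all genes and 7 had an unadjusted p under 0.05. Adjusted over the list alone 3 were lower and 1 higher (median -0.92, camera adjusted p = 0.0172, and adjusted p = 0.372 with an estimated correlation), and the list did not pass without Vortex replicate 1 (0.207).

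In the interferon response list 2 of 33 fell, 0 rose and 31 did not pass, with 11 lower and 1 higher adjusted over the list alone (median -1.06, adjusted p = 2.25e-09, and adjusted p = 0.409 with an estimated correlation). There were 17 lower and 1 higher without Vortex replicate 2 (median -0.59, adjusted p = 1.85e-09, and adjusted p = 0.224 with an estimated correlation). Ifit1bl1, an interferon-induced gene, fell by 3.27 on the log2 scale (SE 0.48). In the cell cycle list 9 of 40 fell and 0 rose, with 12 lower adjusted over the list alone (median -0.44, adjusted p = 3.01e-09, and adjusted p = 0.409 with an estimated correlation), and without Vortex replicate 2 there were 30 lower (median -0.93, adjusted p = 9.31e-22, and adjusted p = 0.224 with an estimated correlation). Mki67 fell by 2.13 (SE 0.30) and Cenpe, a kinetochore motor, by 2.35 (SE 0.37). Chl1, a neural adhesion molecule, fell by 3.45 (SE 0.57). The calls of Ifit1bl1, Mki67, Cenpe and Chl1 ended without any 1 HSS library (adjusted p up to 0.0817, 0.0781, 0.0825 and 0.0843). Mesenchymal markers (1 of 23 higher, 0 lower, 2 and 2 adjusted over the list alone, median -0.34, adjusted p = 0.319) and smooth muscle genes (0 of 12 higher, 2 lower, the same adjusted over the list alone, median -0.13, adjusted p = 0.384) did not pass as lists by camera. Fry called the smooth muscle list lower (adjusted p = 0.0176). Leaving out Vortex replicate 2, mesenchymal markers had 6 higher and 5 lower (median 0.15, camera adjusted p = 0.25). Smooth muscle genes then had 2 higher and 2 lower (median -0.24, camera adjusted p = 0.674). Acta2 (-0.54 ± 0.50), Fn1 (-0.43 ± 0.25), Snai1 (0.50 ± 0.26), Snai2 (1.75 ± 0.52), Edn1 (1.77 ± 0.81) and Mmp9 (-0.33 ± 0.73) did not pass either, with adjusted p = 0.538, 0.31, 0.259, 0.0736, 0.201 and 0.809, and Snai2 passed without Vortex replicate 1 (0.023).

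Over all genes, 1111 differed between Vortex and HSS, 690 higher and 421 lower (62.1% higher), and 841 changed by at least 2-fold. A fit of only the HSS and Vortex libraries called 66 genes. The group ranges did not overlap for 5735 genes (36.4%), where chance gives 10% on average, again not a test. With library totals the split was 458 higher and 542 lower (45.8% higher), with limma-voom 52.0% were higher, and with limma on log2 FPKM 33.4% and 37.7%. The count was 25, 26 and 26 without HSS replicate 1, 2 and 3, 331 and 587 without PSS replicate 1 and 2, 2440 without Vortex replicate 1 and 3887 (2260 higher and 1627 lower) without Vortex replicate 2. Of 36 lists 16 passed with the preset correlation and, by camera, 0 with an estimated one (4 at an unadjusted p under 0.05), while fry called 13. Of the 16 fry did not call endothelial identity (adjusted p = 0.116), cell cycle (0.0577), oxidative phosphorylation (0.0682), Notch (0.19), angiogenic genes (0.0682) and actin cytoskeleton (0.0658). Fry alone called antigen presentation (0.00179) and p53 and senescence (0.0295) higher and smooth muscle genes (0.0176) lower. Without Vortex replicate 2, 18 passed with the preset correlation and 0 of them with both. Those that did not pass by camera with all libraries were leukocyte adhesion and chemokines (0.00256), antigen presentation (0.0362), matrix proteases and inhibitors (0.000134), glycolysis and hypoxia (0.00223) and macrophage and leukocyte markers (0.00225), all higher in Vortex.

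The last comparison asks whether both flow conditions differ from PSS in the same genes. Of the genes called in HSS against PSS and in Vortex against PSS, 607 moved in the same direction, 400 higher and 207 lower, and 12 in opposite directions. Independent lists of these sizes would share 54.9 higher and 29.3 lower genes. Because both comparisons use the same PSS libraries, pairs without any true difference were simulated 20 times. They gave at most 0 shared calls by edgeR's adjusted p, and 168 on average at an unadjusted p under 0.05, where the data gave 1816. Adjusted p-values call few genes where none differ, so the 0 cannot show how many shared calls the common PSS libraries add. The simulations also gave each gene the same spread in all groups, unlike the data. Across genes the fold changes correlated at r = 0.56, against 0.50 in the simulations, and their covariance was 0.550 against 0.123. There were 2789 shared and 119 opposite calls without Vortex replicate 2. The count was 141, 228 and 258 without PSS replicate 1, 2 and 3 and 176, 179 and 172 without HSS replicate 1, 2 and 3. With 3 PSS libraries the controls cannot be divided into separate sets of 2 or more, so part of the excess can come from sharing them. Ccl2, Ccl20, Nos2, Fyb1, Tap1, H2-D1, P4ha2, Srxn1 and Csf1r rose and Idi1 and Mgp fell in both.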

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

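Removing the GC trend, leaving out the libraries of the group not compared, and list tests without Vortex replicate 2 were chosen after the result was seen. The counts of changed genes stayed within 1.5 times their value with DESeq2 size factors, library totals, the filter of 1 CPM in 3 libraries, limma-voom, limma on FPKM, the 2-fold minimum and the GC trend removed, and, except for Vortex against HSS (713), with no filter beyond 1 count. Other values follow in the order HSS against PSS, Vortex against PSS and Vortex against HSS. With the replicate number as a block they were 772, 1258 and 357, although the numbers do not pair the samples (5 of 9 correlated best with their own number, with correlations from -0.123 to 0.118). With the DESeq2 Wald test they were 2456, 3489 and 2700, where the cause was not tested. With only the 6 libraries compared they were 6233, 74 and 66, fits without the Vortex, the HSS and the PSS libraries in that order. The main fit shares 1 spread per gene among groups of unequal spread. Chi-square per degree of freedom between replicates was 2.10 to 2.80 in HSS, 6.49 to 68.0 in PSS and 68.0 to 419 in Vortex. With the GC trend removed and Vortex replicate 2 left out the counts of changed genes were 4800, 5968 and 4262. Leaving out each library gave 285 to 4730, 519 to 5888 and 25 to 3887. Calls shared by both comparisons with PSS were 1236 with the DESeq2 Wald test, 343 with the block and 141 to 2789 leaving out each library. With the GC trend removed the test of the mitochondrially encoded list, not called and pointing downward with medians of 0.02 and 0.01, pointed upward, with medians of 1.15 in Vortex against PSS (adjusted p = 0.000444) and 1.06 in Vortex against HSS (0.000972). It did not pass with Vortex replicate 2 left out as well (0.52, adjusted p = 0.158, and 0.30, adjusted p = 0.0808). With the GC trend removed mt-Nd2 reversed to 0.74 in Vortex against PSS, where the cause was not tested. Leaving out each library, the values of Vortex against PSS ran from -1.75 to 0.46 for Klf2, -0.88 to 1.13 for Nos3, -0.57 to 0.64 for Cdh5, -4.81 to 1.73 for Cldn5, and -0.79 to -0.20 for the median of pericyte and fibroblast markers, with the lowest value of those genes and the reversed list test without Vortex replicate 2. Of the named genes called, 35 of 88, 55 of 95 and 4 of 81 kept their call whichever library was left out. Removing the GC trend ended 10, 18 and 10 of these calls, no filter beyond 1 count 23, 14 and 24, and the block 17, 13 and 42. In the simulations a smaller spread raised the share called of the 2-fold changes more than that of the 4-fold ones, and depth was not varied.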

Other observations

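The tests of a swapped library, of vortex flow itself, of a smaller share of endothelial cells, of 1 culture behind 3 libraries and of leukocytes were chosen after the result was seen, as were the genes of the next paragraph. The tests of the GC trend and of the Y-linked genes likewise address patterns that were first seen in these data.

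A few genes, which were not tested as a list, differed between groups or set Vortex replicate 2 apart from the other Vortex libraries. Mest, an imprinted gene expressed from the paternal copy, was at 674 to 713 CPM in the PSS libraries, 50.3 to 55.8 in HSS, 29.7 and 81.4 in Vortex replicates 1 and 3 and 1104 in Vortex replicate 2. Igf2, an imprinted fetal growth factor, was at 36.7 to 47.8 CPM in PSS, 0.707 to 1.68 in HSS, 2.84 and 5.68 in Vortex replicates 1 and 3 and 39.2 in Vortex replicate 2. H19, the noncoding neighbour of Igf2, was at 2233 CPM in Vortex replicate 2 and at most 2.47 in the other 8 libraries. Peg10, a retrotransposon-derived imprinted gene, was at 1199 to 1853 CPM in PSS and 3938 to 4047 in HSS. Pdgfra, a growth factor receptor of mesenchymal cells, was at 467 and 332 CPM in Vortex replicates 1 and 3, 21.4 in Vortex replicate 2 and 68.0 to 76.4 in the PSS and HSS libraries. Dcn, a matrix proteoglycan of fibroblasts, was at 40.9 and 44.9 CPM in Vortex replicates 1 and 3, 0.381 in Vortex replicate 2, 3.55 to 4.78 in PSS and 8.30 to 8.86 in HSS.

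Vortex replicate 2 lay apart from the other Vortex libraries in endothelial genes. A bias in counting by GC content would leave little of the difference once the trend is removed, but the median over the 29 endothelial identity genes was 2.81 before and 2.67 after removal (interquartile range 1.66 to 3.85). A swap with a PSS or HSS library would leave a partner out of place, and 0 of the 6 PSS and HSS libraries correlated best with another group. By the same measure the Vortex libraries did not hold together. Vortex replicate 2 correlated best with PSS replicate 1 (0.915535, against 0.915526 with Vortex replicate 3). Vortex replicate 3 correlated best with HSS replicate 2 (0.962382, against 0.962305 with Vortex replicate 1). Cells of another stock that lost most of the Y chromosome would keep all 4 Y-linked genes low, but their differences moved from between -2.74 and -2.10 to between -1.06 and -0.27 when the GC trend was removed, so a smaller loss stays open. Vortex flow itself cannot be told apart from the handling of single samples, since 1 of the 3 Vortex libraries had an endothelial median above the PSS mean, and a single wrong label, a sample from outside the series or a separate culture may also account for it and was not tested.

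Of 29 endothelial identity genes 14 were lower in HSS than in PSS and 15 did not pass, and the list call was lost with an estimated correlation (adjusted p = 0.352). With Vortex replicate 2 left out 25 were lower and 1 higher, and the call was again lost with an estimated correlation (adjusted p = 0.136). The GC trend does not carry this difference, since the list median was -2.96 before and -3.07 after removal. A smaller share of PSS-like cells among cells lacking these genes would lower them all alike, but over the 28 with at least 10 CPM in PSS the log2 fold changes ran from -10.44 to 0.53 (SD 2.49). Pericyte and fibroblast markers did not rise as a list (median -0.04, 0 of 17 higher and 3 lower). These values address only cells that lack all these genes. A mix with cells that express some of them could also give unequal falls and was not tested. That 1 culture was sequenced as 3 libraries cannot be told apart from separate, very similar cultures: the highest chi-square per degree of freedom between HSS libraries was 2.80, where the closest PSS pair had 6.49, and the labels do not decide it. Shear stress and a culture that had changed before the flow both remain candidate explanations.

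In HSS against PSS 14 of 30 leukocyte adhesion and chemokine genes and 15 of 33 interferon genes were higher, and both list calls were lost with an estimated correlation (adjusted p = 0.193 each). With Vortex replicate 2 left out 23 and 32 were higher and 0 lower, and both lists passed with an estimated correlation (adjusted p = 0.0289 each). The medians of both lists also lay above PSS in Vortex replicates 1 and 3. The macrophage and leukocyte marker list of 11 genes was called higher too, in HSS and in Vortex (camera adjusted p = 0.0491 and 0.000126). Adjusted over the list alone it had 4 higher and 2 lower in HSS, and 8 higher and 0 lower in Vortex. Leukocytes in the cultures would bring all their abundant transcripts, but of the 5 leukocyte genes found in the table, all except Csf1r (up to 18.9 CPM) stayed at or below 0.368 CPM in the HSS libraries and Vortex replicates 1 and 3. Other marker genes did rise. Without Vortex replicate 2, 6 of 12 members of the marker list were called higher and 0 lower in Vortex than in HSS. Among them were Cd53 (log2 fold change 5.87), Lcp1 (2.46) and Cd68 (2.65). The 5 genes do not cover these rises, so leukocytes in the Vortex cultures are not excluded. The GC trend does not carry the difference either, since the median of the leukocyte adhesion and chemokine list in HSS was 1.41 before and 1.41 after its removal. A response of the endothelial cells to both flows may remain, as a hypothesis from the same data, together with any difference in culture that followed the groups.

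Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. By edgeR, 1 of 10 splits, the real one, gave as many calls in each comparison: 1242, 2107 and 1111, with 0 as the highest count of the other splits in each case. At an unadjusted p under 0.05, the real splits gave 3693, 4706 and 4236 genes and the highest of the others 209, 2451 and 1163. Each of the other splits mixes libraries of both groups, so any difference between the groups widens the spread within its parts and lowers its count. The counts of 0 were thus largely set in advance. They give no evidence that flow, rather than another difference between the groups, made the calls.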
